A study of Homo sapiens with 12 samples.

How the data were processed

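The 12 libraries were made from human pulmonary artery endothelial cells, primary cells that line the artery from the heart to the lung, bought commercially and grown in EGM2 medium, per the labels. Cells received a non-targeting siRNA (siNT) or siRNA against LATS1 and LATS2 (siLATS). No second siRNA or rescue is among the libraries, so other effects of the siLATS molecules could not be separated from loss of LATS1 and LATS2. They were then kept static or under a shear stress of 10 dyn/cm2 in a perfusion slide for 24 h. RNA was pooled from 3 to 4 slides per condition and had an RNA integrity number of 10. Libraries were made from 1.5 µg of RNA with a stranded mRNA kit, per the labels.

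The deposited values were raw read counts per gene for each library, held in 12 columns, per the file headers and the labels. The genome build was GRCh38, and the submitters' processing notes name FastQC 0.11.8 and MultiQC 1.7. The aligner, the counting rule, its strand setting and the annotation release were not given in the sources used here. The same table holds 36 further columns of normalized values per library, which were not used. Because the strand setting was not stated, values of antisense or overlapping genes are uncertain. Near-identical copies such as HSPA1A and HSPA1B, or HBA1 and HBA2, can share reads and are uncertain too.

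The table held 60676 genes. XIST, TSIX and the genes of chromosome Y, 524 in all, were left out. Low counts were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 15498 genes. Library sizes were scaled by TMM (factors 0.924 to 1.05), and counts scaled to library size (CPM) used those sizes. All 12 libraries entered 1 fit with 4 groups of 3, tested with edgeR's quasi-likelihood test on 8 residual degrees of freedom, with Benjamini-Hochberg adjustment over the genes tested. A call means an adjusted p under 0.05, and fold changes are on the log2 scale with their standard errors. The 5 comparisons were flow against static in siNT and in siLATS, siLATS against siNT in static and in flow, and the interaction, which is the flow effect in siLATS less that in siNT. Total counts per library, rounded to 6 digits, were 28683200 to 34221900. At this depth replicates of a group differed by more than sampling noise, so that no 2 libraries were counted as 1. Chi-square per degree of freedom over genes was 9.95 to 50.2 between replicates of static groups and 39.2 to 93.7 between those of flow groups. The fit on all 12 libraries took 1 spread per gene for all 4 groups. A p-value therefore does not measure the spread of the compared libraries alone. Nothing in the labels says that replicates came from separate donors or cultures beyond separate experiment days. The p-values therefore measure only the spread between these samples, which may be technical.

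The 3 replicate numbers pair the samples, because per the labels each number marks 1 experiment day shared by the 4 groups. Deviations from the group means of libraries with the same number correlated across genes with r of 0.0872 to 0.540 (median 0.253, 18 pairs, 16 above 0.1). Libraries with different numbers gave -0.415 to 0.0805 (median -0.0923), and 12 of the 12 libraries correlated best with their own number. The design without the replicate number was kept as the primary one, as fixed before the data were examined. The design with the number as a block (6 residual degrees of freedom) was an alternative.

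Of 34 gene lists from general knowledge, holding 486 distinct genes, 33 had at least 5 genes tested. Some lists share genes, so their calls are not independent. Members also held by another list were 10 of 15 tip cell genes, 8 of 13 pulmonary arterial hypertension genes and 7 of 17 KLF2/KLF4 programme genes. They were tested with limma's camera on a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with an estimated correlation and with fry. The median, the mean and the camera test had the same sign in each of the lists called. The groups, comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. That rule took 3 kinds of gene. The first were the 10 genes with the largest rise and the 10 with the largest fall among called genes, with a mean of at least 5 CPM in the higher group, the same sign in all 3 pairs and no clone or locus name. The second were the 4 members with the smallest p of each list named, plus called members that went against the list. The last were LATS1, LATS2, YAP1, WWTR1, CCN1, CCN2, ANKRD1, KLF2, KLF4, NOS3 and EDN1, named in every comparison. A further 4 lists, of red cell, neutrophil, lymphocyte and platelet genes, were written after blood-cell transcripts were seen in 1 library.

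Alternatives were RLE and upper-quartile scaling, no filter and a stricter one (1 CPM in at least 6 libraries), DESeq2, limma-voom, the replicate block, fits on only the groups compared, and fits without each library or replicate number (for lists and correlations, without each replicate number). Added after seeing the data were fits without the 2 libraries of highest mitochondrial share (siNT flow replicate 3 and siLATS flow replicate 3), list tests and correlations without siLATS static replicate 1, and fits without the genes raised in the library with blood-cell transcripts. Relations between comparisons were set against 20 simulations with no effect and 20 with equal effects. Both drew each gene independently, with the same spread in all groups and no effect of the experiment day. Those with equal effects took as true the effects fitted to these data without an interaction, noise included. The fits were tested on simulated data in which 200 genes were changed. For the flow effect in siNT (15118 genes) 38.8%, 77.6% and 98.5% of genes changed by 1.5-fold, 2-fold and 4-fold were recovered, with 10 false calls. The knockdown effect in static (15107 genes) gave 28.4%, 80.6% and 95.5% with 5 false calls, and the interaction (15124 genes) gave 13.4%, 49.3% and 93.9% with 7 false calls. With 3 lists shifted by 1.5-fold for the knockdown effect in static (15498 genes), camera with the preset correlation called all 3 shifted lists and 1 other, camera with an estimated correlation called 3 and 0 others, and fry called 2 and 0 others. Genes were drawn independently there, so these counts do not show how often correlated genes give false list calls. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, data.table (1.17.8) and matplotlib 3.10.9.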

Results

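Messenger RNA was sequenced from human pulmonary artery endothelial cells to ask how the Hippo kinases LATS1 and LATS2 shape the response of these cells to flow. The 12 libraries formed 4 groups of 3, siNT static, siNT flow, siLATS static and siLATS flow, and each replicate number was 1 experiment day. Total counts per library, rounded to 6 digits, were 28683200 to 34221900, and 14507 to 15732 genes had at least 10 counts. Mitochondrial genes held 2.45% to 3.91% of counts, with the highest shares in siLATS flow replicate 3 (3.91%) and siNT flow replicate 3 (3.50%). Ribosomal protein genes held 4.56% to 5.00% of counts in the static libraries and 2.68% to 3.73% in the flow libraries. In the static knockdown library of replicate 1, globin transcripts made up 0.714% of counts, against at most 0.00725% in any other library.

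Both targets were reduced in every siLATS library. LATS1 (chromosome 6, 149658153 to 149718105, GRCh38) averaged 40.7 ± 2.42 CPM (SD, n = 3) in siNT static and 7.57 ± 1.53 in siLATS static, and 44.5 ± 3.20 in siNT flow and 6.70 ± 1.56 in siLATS flow. LATS2 (chromosome 13, 20973036 to 21061586) averaged 115 ± 5.98 CPM in siNT static and 27.0 ± 3.61 in siLATS static, and 172 ± 15 in siNT flow and 29.0 ± 3.51 in siLATS flow. The highest siLATS library had 9.31 CPM of LATS1 and 32.8 of LATS2, below the lowest siNT library at 38.5 and 108. In edgeR's quasi-likelihood test, the log2 fold change of LATS1 was -2.43 in static (SE 0.171, adjusted p = 1.98e-05) and -2.73 in flow (SE 0.173, adjusted p = 1.93e-05). That of LATS2 was -2.09 in static (SE 0.116, adjusted p = 5.66e-06) and -2.57 in flow (SE 0.118, adjusted p = 2.06e-06).

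**Figure D1:**
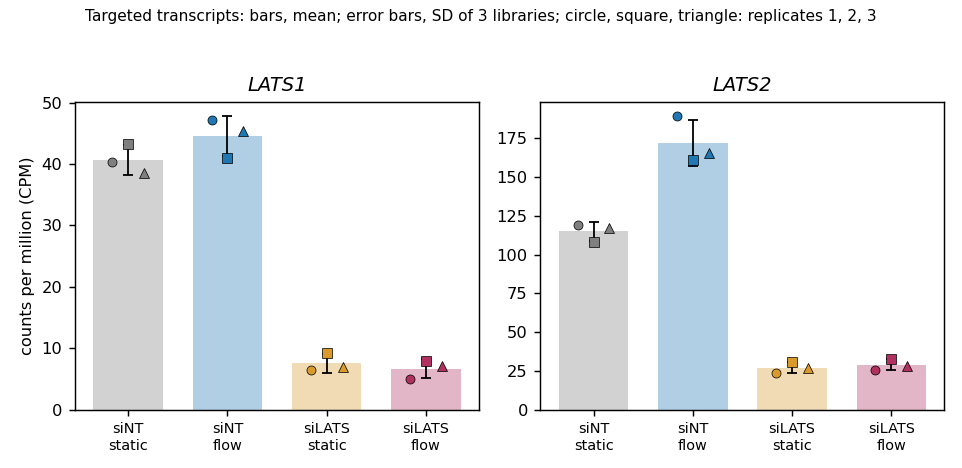
LATS1 and LATS2 counts scaled to library size (CPM) in the 4 groups; bars are means, error bars are SD (n = 3) and points are single libraries. LATS1 averaged 7.57 and 6.70 CPM in the siLATS groups against 40.7 and 44.5 in the siNT groups.

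**Figure D2:**
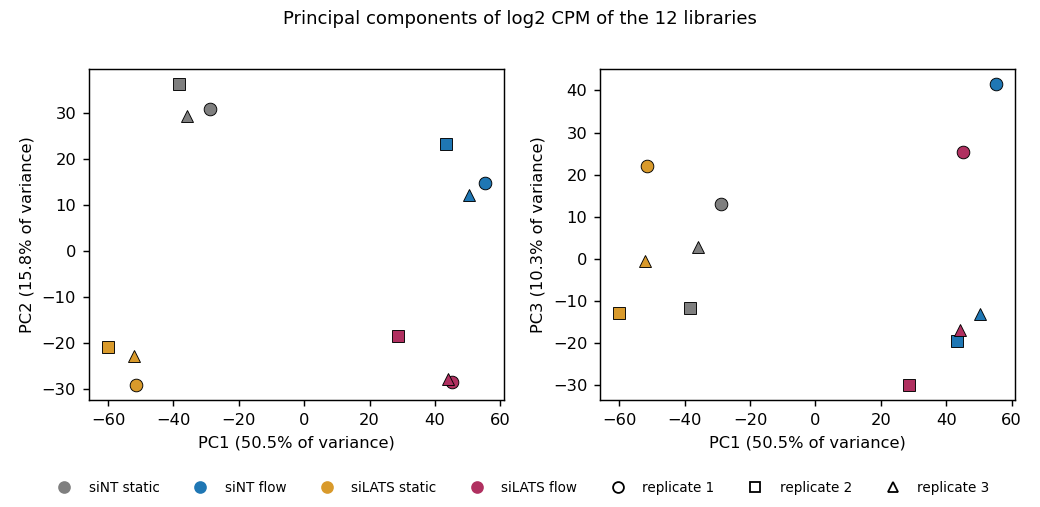
Principal components of log2 CPM over the genes tested, with the first component (50.5% of the variance) on the x axis of both panels and the second (15.8%) and the third (10.3%) on the y axes; each point is 1 library, coloured by group. The first component parted flow from static libraries and the second parted siLATS from siNT.

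The effect of 24 h of flow was first measured in cells with the control siRNA. Flow raised transcripts of the flow-responsive transcription factors KLF2 and KLF4 and of endothelial nitric oxide synthase, NOS3, and lowered some of the interferon-induced and inflammatory genes. Both of the latter list calls were lost with an estimated correlation. KLF4 (chromosome 9, 107484852 to 107490482) rose from a mean of 3.54 to 63.5 CPM (log2 fold change 4.17, SE 0.195, adjusted p = 6.05e-07). KLF2 (chromosome 19, 16324817 to 16327874) rose from 38.2 to 144 CPM (1.91, SE 0.115, adjusted p = 1.58e-06), and NOS3 (chromosome 7, 150991017 to 151014588) from 64.9 to 223 CPM (1.78, SE 0.101, adjusted p = 1.11e-06). EDN1, which encodes the vasoconstrictor endothelin-1, fell from 682 to 274 CPM (-1.31, adjusted p = 0.00297). Across the 15498 genes tested, 2789 were higher and 2741 lower under flow, of which 619 and 911 changed by at least 2-fold. Upper-quartile scaling moved the split to 2137 higher and 3527 lower, with a shift of the median gene of -0.09.

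The largest rises in siNT besides KLF4 were CD180, a Toll-like receptor family member (7.96, mean 0.0614 to 16.5 CPM), DDIT4L (4.59), MYOM3 (4.58), JPH4 (4.45), CCN3, a secreted matricellular protein (4.43, 1.14 to 24.7 CPM), SEMA7A (4.37), P2RX5 (4.28), ADM2 (4.28) and ALPL (4.12). The largest falls were in the chemokine CXCL6 (-7.15, 8.29 to 0.0546 CPM), SLC7A14 (-6.92), INHBB (-6.01), MX2 (-5.91), the gap junction gene GJA4 (-5.49), the cytokine LTB (-5.37), IFIT1 (-4.92), DHRS3 (-4.75), MX1 (-4.58, 40.3 to 1.69 CPM) and the monocyte chemokine CCL2 (-4.32, 164 to 8.20 CPM). Each had the same sign in all 3 pairs, and an adjusted p of at most 0.00716 apart from ADM2 (0.0337). The call of ADM2 was lost without any siNT static library or siNT flow replicate 1 (up to 0.337).

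Among the lists fixed in advance, the KLF2/KLF4 programme had 11 of 17 members higher and 1 lower (12 and 1 adjusted over the list alone, median log2 fold change 1.91; camera adjusted p = 1.58e-16, and adjusted p = 0.00141 with an estimated correlation). The lower one was THSD4 (-0.90). NRF2 targets, antioxidant genes, had 12 of 14 higher and 0 lower (13 and 0 adjusted over the list alone, median 1.16; adjusted p = 3.26e-11, and adjusted p = 0.321 with an estimated correlation), among them HMOX1 (3.68), SLC7A11 (2.35), NQO1 (2.08) and GCLM (1.68). Heat shock genes had 8 of 10 higher and 1 lower (8 and 1 adjusted over the list alone, median 0.47; adjusted p = 1.63e-05, and adjusted p = 0.198 with an estimated correlation), with HSPA1B at 1.31, HSPA1A at 1.16, HSPH1 at 0.64, BAG3 at 0.60 and the lower HSPD1 at -0.18.

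Interferon-stimulated genes had 16 of 22 members lower and 0 higher, the same count adjusted over the list alone (median -1.29; adjusted p = 4.83e-09, and adjusted p = 0.370 with an estimated correlation), including IFI44L (-2.71) and CXCL11 (-3.81). NF-kB inflammatory genes had 9 of 17 lower and 0 higher (9 and 1 adjusted over the list alone, median -1.13; adjusted p = 5.64e-05, and adjusted p = 0.363 with an estimated correlation), including the neutrophil chemokine CXCL1 (-3.77), the adhesion molecule SELE (-4.65) and CX3CL1 (-4.01). SRF/MRTF cytoskeletal genes had 8 of 16 lower and 0 higher, again the same adjusted over the list alone (median -0.33; adjusted p = 0.000474, and adjusted p = 0.416 with an estimated correlation), with FHL2 at -1.55, TPM2 at -1.41, CNN2 at -0.79 and ZYX at -0.59. Genes known to be repressed by flow had 5 of 12 lower and 2 higher, also adjusted over the list alone (median -0.44; adjusted p = 0.000499, and adjusted p = 0.321 with an estimated correlation). ANGPT2 (-2.52), BMP4 (-2.15) and TXNIP (-1.58) fell, and ESM1 (0.67) and INSR (0.46) rose.

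YAP/TAZ-TEAD targets, transcripts driven by the coactivators that LATS kinases restrain, had 10 of 21 lower and 4 higher under flow in siNT (11 and 4 adjusted over the list alone, median -0.36; adjusted p = 0.0242, adjusted p = 0.653 with an estimated correlation and 0.0791 without replicate 2). TGFB2 (-2.23), NUAK2 (-1.52), FJX1 (-1.21) and AJUBA (-0.72) fell, and F3 (1.29), MYOF (0.62), ANKRD1 (0.59, adjusted p = 0.0380) and PTPN14 (0.25) rose. CCN2 was lower (-0.63, adjusted p = 0.0252), and CCN1 had -0.45 (adjusted p = 0.0557, and 0.0327 with the replicate block). CCN1 was called without siNT flow replicate 3 or siLATS flow replicate 1 or 3 (adjusted p up to 0.0428). YAP1 itself was lower (-0.90, adjusted p = 0.0176) and WWTR1, which encodes TAZ, had -0.17 (adjusted p = 0.460). The calls of CCN2, YAP1 and ANKRD1 lay near the threshold and were lost when single libraries were left out. That of CCN2 was lost without any of the 3 siNT static libraries or siNT flow replicate 1 or 2 (adjusted p up to 0.0870), and that of YAP1 without siNT static replicate 2 or siNT flow replicate 1 or 3 (up to 0.0721). That of ANKRD1 was lost without any siNT static library, siNT flow replicate 1 or 3, or siLATS static replicate 3 (up to 0.134).

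Another 3 lists were called. Integrin and focal adhesion genes had 7 of 17 higher and 1 lower (8 and 1 adjusted over the list alone, median 0.41; adjusted p = 0.0103, and adjusted p = 0.653 with an estimated correlation), with TNS3 at 1.3, ITGA6 at 1.28, ITGA2 at 1.04 and ITGB3 at -1.84. Immediate early genes had 5 of 13 higher and 2 lower, also adjusted over the list alone (median 0.63; adjusted p = 0.0216, adjusted p = 0.321 with an estimated correlation and 0.0574 without replicate 3), with NR4A1 at 3.45, IER2 at 0.86, JUNB at 0.79 and MYC at -0.63. Targets of p53 had 8 of 15 lower and 1 higher (8 and 2 adjusted over the list alone, median -0.35; adjusted p = 0.0304, adjusted p = 0.363 with an estimated correlation, 0.0821 with the replicate block and 0.0612 without replicate 3), with FDXR at -1.06, ZMAT3 at -0.71, MDM2 at -0.69, SESN1 at -0.66 and FAS at 0.56. With the replicate block, cholesterol synthesis genes (adjusted p = 0.0841, block 0.00205) and hypoxia-inducible genes (0.0698, block 0.0161) were also called, both toward higher levels. With an estimated correlation neither was called (adjusted p = 0.927 and 0.321).

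**Figure D3:**
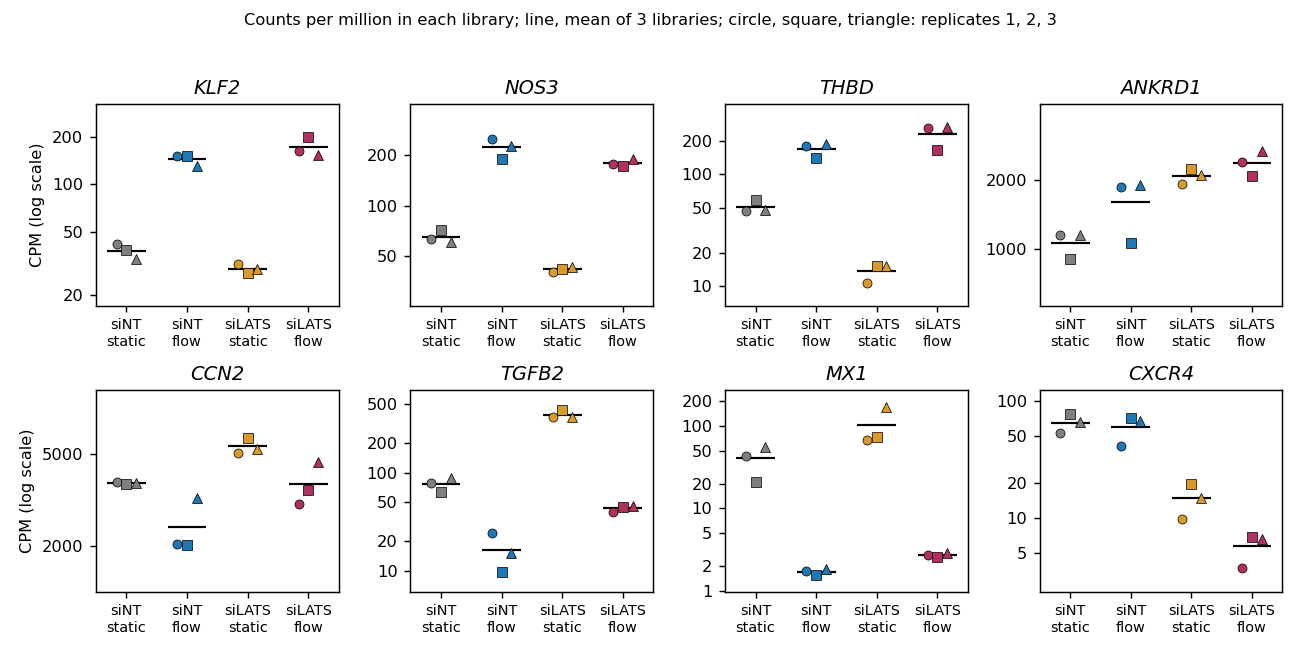
CPM on a log axis for KLF2, NOS3, THBD, ANKRD1, CCN2, TGFB2, MX1 and CXCR4 in each library; points are single libraries in the 4 groups. KLF2 averaged 38.2 CPM in siNT static and 144 in siNT flow, and MX1 averaged 40.3 and 1.69.

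The effect of siLATS was then measured in static cells. Some interferon-stimulated genes and YAP/TAZ-TEAD targets were higher than in siNT, and some angiogenic, endothelial identity and flow-induced genes were lower. Without a second siRNA or a rescue, effects of the siRNA other than loss of LATS1 and LATS2 could not be separated in any comparison. Of its list calls 0 held with an estimated correlation. IGFBP3, which binds insulin-like growth factors, rose from a mean of 47.6 to 609 CPM (log2 fold change 3.68, SE 0.328, adjusted p = 6.03e-05), and the growth factor TGFB2 from 77.3 to 392 CPM (2.34, SE 0.249, adjusted p = 0.000147). THBD, the anticoagulant receptor thrombomodulin, fell from 51.3 to 13.8 CPM (-1.89, SE 0.206, adjusted p = 0.000178), and the chemokine receptor CXCR4 from 65.2 to 14.7 CPM (-2.15, SE 0.293, adjusted p = 0.000702). In all, 991 genes were higher and 1285 lower (1670 and 2069 with the replicate block), of which 255 and 375 changed by at least 2-fold. The count of higher genes was 530, 576 and 556 without siNT static replicate 1, 2 and 3 and 597 without siLATS static replicate 3, and the count of lower genes was 823 without siNT static replicate 1. Without replicate 3 the counts were 198 and 391, and in a fit on only the static libraries 1601 and 1840.

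The largest rises besides IGFBP3 were in PLCE1-AS1, an antisense transcript and so uncertain here (5.78), the glycosyltransferase B3GALT2 (4.47), LRRC7 (3.36), the elastin gene ELN (3.32), the insulin receptor substrate IRS1 (3.27), TYRP1 (3.21), the sulfatase SULF1 (3.07), BEX1 (3.01) and the proteoglycan SDC2 (2.98). The largest falls were in the decoy receptor TNFRSF6B (-3.43), MAMDC2 (-3.06), the endothelial protocadherin PCDH12 (-2.95), the receptor KIT (-2.83), HTRA3 (-2.83), the angiotensin-converting enzyme ACE (-2.67), RASD1 (-2.61), PALD1 (-2.56), HLX (-2.50) and LINC00702 (-2.48). Each had an adjusted p of at most 0.00753 apart from ELN (0.0121) and KIT (0.0239). The call of ELN was lost without siNT static replicate 1 or 3 (up to 0.0588), and that of KIT without siNT static replicate 2 or 3 or siLATS static replicate 1 or 3 (up to 0.0886).

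YAP/TAZ-TEAD targets had 6 of 21 members higher and 1 lower (9 and 2 adjusted over the list alone, median 0.05; adjusted p = 0.00804, and adjusted p = 0.532 with an estimated correlation). IGFBP3, TGFB2, ANKRD1 (0.97, 1065 to 2081 CPM, adjusted p = 0.00779), CRIM1 (0.72) and AMOTL2 (0.54) rose and NT5E (-0.73) fell. CCN2 had 0.53 (adjusted p = 0.0920, and 0.0226 with the replicate block) and was called without siNT flow replicate 3 (adjusted p = 0.0313). CCN1 had -0.12 (adjusted p = 0.703), YAP1 -0.15 (0.753) and WWTR1 -0.15 (0.617). SRF/MRTF cytoskeletal genes had 4 of 16 higher and 1 lower (6 and 1 adjusted over the list alone, median 0.16; adjusted p = 0.0135, adjusted p = 0.536 with an estimated correlation and 0.0710 without replicate 2), with TPM1 at 1.28, CNN2 at 0.57, CALD1 at 0.49 and TPM4 at -0.43. The call of TPM4 was lost without siNT static replicate 1 or 3 or siLATS static replicate 1 (adjusted p up to 0.0792).

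Interferon-stimulated genes had 10 of 22 higher and 0 lower (18 and 0 adjusted over the list alone, median 1.03; adjusted p = 1.36e-08, and adjusted p = 0.402 with an estimated correlation), with IFI6 at 1.79, IFI44L at 1.67 and IFI44 at 1.02. Among smooth muscle and pericyte markers, 1 of 5 was higher (3 adjusted over the list alone, median 1.04; adjusted p = 0.0220, adjusted p = 0.325 with an estimated correlation and 0.0998 without replicate 2). It was PDGFRB (1.98, mean 0.272 to 1.09 CPM), whose call was lost without any siNT static library or siLATS static replicate 2 or 3 (adjusted p up to 0.0992).

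Tip cell and angiogenic genes had 11 of 15 lower and 1 higher, also adjusted over the list alone (median -1.0; adjusted p = 4.80e-06, and adjusted p = 0.172 with an estimated correlation). CXCR4, the placental growth factor gene PGF (-1.73) and the VEGF receptor gene KDR (-1.08) fell, and IGFBP3 was the one that rose. Endothelial identity and junction genes had 7 of 18 lower and 0 higher (9 and 0 adjusted over the list alone, median -0.36; adjusted p = 6.02e-05, and adjusted p = 0.203 with an estimated correlation), with the tight junction gene CLDN5 at -2.15, PECAM1 at -0.73 and ICAM2 at -0.70. Notch and arterial genes had 5 of 17 lower and 2 higher (8 and 2 adjusted over the list alone, median -0.31; adjusted p = 0.0135, and adjusted p = 0.532 with an estimated correlation), with UNC5B at -2.19, the VEGF co-receptor gene NRP1 at -1.07 and the ligand genes JAG1 at 0.84 and EFNB2 at 0.93.

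The KLF2/KLF4 programme had 8 of 17 lower and 1 higher in static knockdown cells (9 and 1 adjusted over the list alone, median -0.53; adjusted p = 5.69e-05, and adjusted p = 0.118 with an estimated correlation). CCN3 (-2.65), HMOX1 (-1.91), THBD and NOS3 (-0.64, adjusted p = 0.00149) fell, and ASS1 (1.7) rose. KLF2 itself was lower (-0.38, adjusted p = 0.0437), a call lost without siNT static replicate 1 or 2, siNT flow replicate 2 or any siLATS static library (adjusted p up to 0.159). KLF4 had -0.05 (adjusted p = 0.904) and EDN1 0.29 (0.534). Vasoactive genes had 5 of 13 lower and 2 higher (7 and 3 adjusted over the list alone, median -0.76; adjusted p = 0.0497, adjusted p = 0.305 with an estimated correlation, 0.0802 without siLATS static replicate 1 and 0.124 without replicate 1), with ACE, APLN (-0.76) and NOS3 lower and DDAH1 (0.70) higher. Pulmonary arterial hypertension genes had 3 of 10 lower and 0 higher, also adjusted over the list alone (median -0.10; adjusted p = 0.0497, adjusted p = 0.307 with an estimated correlation, 0.0548 with the replicate block, 0.130 without siLATS static replicate 1 and 0.120 without replicate 1). The 3 were AQP1 (-2.24), KDR and the BMP receptor ACVRL1 (-0.68).

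NF-kB inflammatory genes had 3 of 17 lower and 0 higher in static knockdown cells (5 and 0 adjusted over the list alone, median -0.74; adjusted p = 0.00898, and adjusted p = 0.532 with an estimated correlation). The 3 were RELB (-1.25), TRAF1 (-1.05) and TNFAIP3 (-0.67). RELB lost its call without any 1 of the 6 static libraries (adjusted p up to 0.123) and TRAF1 without siNT static replicate 3 or siLATS static replicate 1 or 3 (up to 0.0607). TNFAIP3 lost it without any siNT static library, siLATS static replicate 1 or 3, siNT flow replicate 3 or siLATS flow replicate 3 (up to 0.157). Immediate early genes had 4 of 13 lower and 1 higher, also adjusted over the list alone (median -0.23; adjusted p = 0.0312, and adjusted p = 0.325 with an estimated correlation), with FOSL1 at -1.31, IER2 at -0.50, JUN at -0.40 and IER3 at 1.25. The list was not called without siLATS static replicate 1 (adjusted p = 0.0802), without replicate 1 (0.122) or 3 (0.0717) or without both libraries of highest mitochondrial share (0.0507). S-phase genes had 1 of 18 lower and 0 higher (0 and 0 adjusted over the list alone; 13 lower with the replicate block, median -0.62; adjusted p = 0.0152, adjusted p = 0.709 with an estimated correlation and 0.107 without siLATS static replicate 1). The 1 was the replication gene MCM3 (-0.74, adjusted p = 0.0320), whose call was lost without any 1 of the 6 static libraries (up to 0.115). With the replicate block, flow-repressed genes (adjusted p = 0.154, block 0.00771), NRF2 targets (0.0972, block 0.0335) and mitotic genes (0.165, block 0.0212) were also called toward lower levels and cholesterol synthesis genes (0.204, block 0.0137) toward higher levels. With an estimated correlation none of the 4 was called (adjusted p of 0.690 to 0.884).

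**Figure D4:**
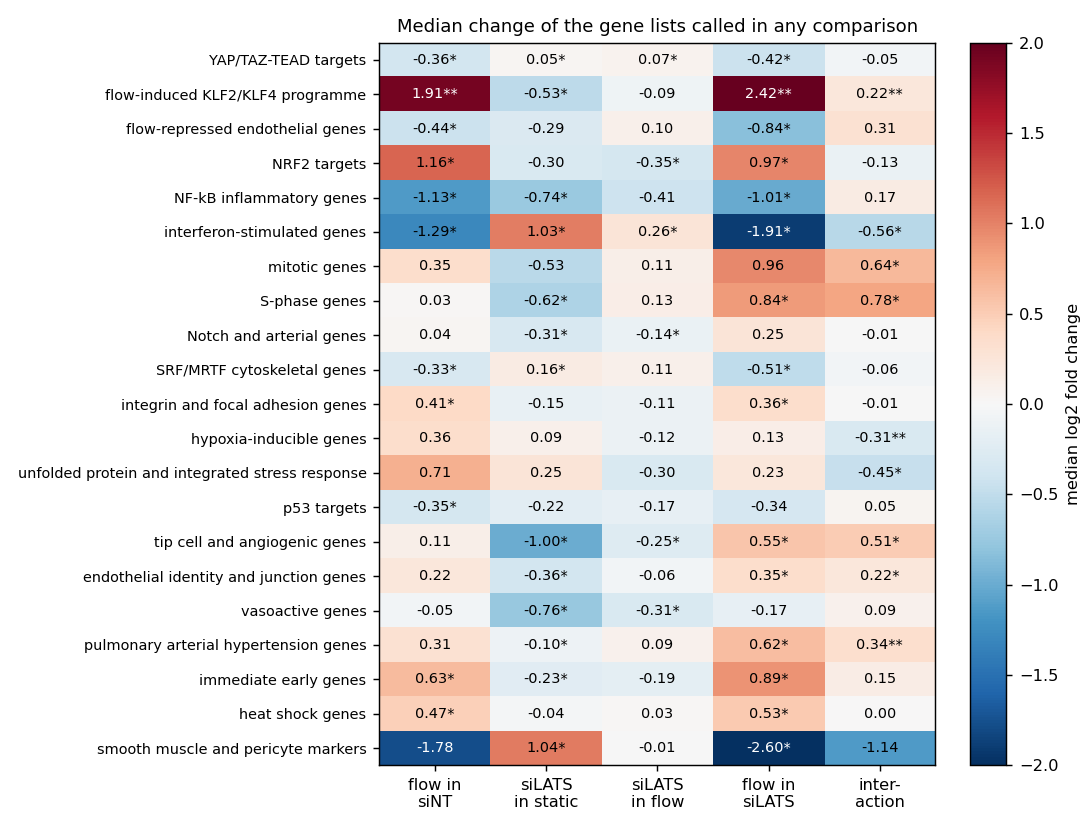
Median log2 fold change of the 21 lists called in at least 1 comparison (list names on the y axis, comparisons on the x axis, colour for the median); 1 star marks a camera call and 2 stars a call that also held with an estimated correlation. The KLF2/KLF4 programme had medians of 1.91 and 2.42 for flow in siNT and siLATS.

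The knockdown was measured again under flow. Again YAP/TAZ-TEAD targets included raised members, and Notch, tip cell and vasoactive genes included lowered ones. The Notch and tip cell lists share the lowered genes CXCR4, UNC5B and DLL4, so they are not separate evidence. CXCR4 fell from a mean of 60.0 to 5.70 CPM (log2 fold change -3.39, SE 0.314, adjusted p = 0.000252), and the prostaglandin synthase genes PTGS1 (-2.16, SE 0.275, adjusted p = 0.00121) and PTGS2 (-2.13, SE 0.237, adjusted p = 0.000626) fell. The glycoprotein hormone gene STC1 had the largest fall (-6.58, 15.9 to 0.163 CPM, adjusted p = 0.00304). In all, 468 genes were higher and 749 lower (994 and 1427 with the replicate block), of which 114 and 168 changed by at least 2-fold. The main fit shares its spread with the static libraries, and a fit on only the flow libraries gave 81 and 206. Without replicate 3 there were 2 and 13. The count of higher genes was 256 without siNT flow replicate 2 and 299 without siLATS flow replicate 1. It was 249, with 383 lower, when both libraries of highest mitochondrial share were left out.

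The largest rises under flow were BEX1 (2.61), TSPAN2 (2.52), SULF1 (2.48), the adrenergic receptor ADRB1 (2.22), MCTP1 (2.07), PRR15 (1.94), BCYRN1 (1.67), GPR65 (1.6), ALDH1A1 (1.59) and IFI6 (1.56). SULF1 lost its call without siNT flow replicate 1 or siLATS flow replicate 2 (adjusted p up to 0.0526), and ALDH1A1 without siNT flow replicate 1 or 3 or siLATS flow replicate 2 (up to 0.0856). BCYRN1, a repeat-derived gene and so uncertain, lost it without any library other than siNT static replicate 1 or 3 (up to 0.102), and IFI6 without siNT flow replicate 1 or 2 or siLATS flow replicate 3 (up to 0.0667). Other large falls were ACE (-2.59, lost without siLATS flow replicate 3 at 0.0518), MAP1A (-2.42), CLMP (-2.32) and ANGPTL2 (-2.15). YAP/TAZ-TEAD targets had 5 of 21 higher and 1 lower (8 and 2 adjusted over the list alone, median 0.07; adjusted p = 0.0156, adjusted p = 0.703 with an estimated correlation and 0.0534 without replicate 2), with TGFB2 at 1.41, CRIM1 at 0.66 and F3 at -0.66. Without siNT flow replicate 2 the higher members AMOTL2 (0.0512) and IGFBP3 lost their calls, and IGFBP3 also without siLATS flow replicate 2 or 3 (up to 0.0869). CCN2 had 0.61 (adjusted p = 0.0781, block 0.0159; called without siNT flow replicate 3 at 0.0119) and ANKRD1 0.57 (adjusted p = 0.112, block 0.0258). CCN1 had 0.00 (adjusted p = 0.996), YAP1 0.02 (0.983), WWTR1 0.15 (0.666), KLF2 0.25 (0.210) and KLF4 0.14 (0.672). EDN1 had 0.58 (0.224, and 0.0264 without siNT flow replicate 3), and NOS3 -0.31 (0.0805, and 0.0231 without siNT flow replicate 2).

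Notch and arterial genes had 4 of 17 lower and 0 higher under flow (6 and 0 adjusted over the list alone, median -0.14; adjusted p = 0.00408, and adjusted p = 0.703 with an estimated correlation), among them CXCR4 and NRP1 (-0.79). The other 2, UNC5B and DLL4, both lost their calls without siNT flow replicate 2 or 3 or siLATS flow replicate 1 or 2 (adjusted p up to 0.0789 and 0.154). DLL4 lost it without any library other than siNT flow replicate 1. Tip cell and angiogenic genes had 5 of 15 lower and 1 higher, also adjusted over the list alone (median -0.25; adjusted p = 0.00408, and adjusted p = 0.703 with an estimated correlation). UNC5B, DLL4 and PGF, 3 of the 5, lost their calls without siNT flow replicate 2 or 3 or siLATS flow replicate 1 (PGF up to 0.0653). The higher one was IGFBP3 (1.29), whose call was lost without siNT flow replicate 2 or siLATS flow replicate 2 or 3 (adjusted p up to 0.0869). Vasoactive genes had 3 of 13 lower and 1 higher (5 and 1 adjusted over the list alone, median -0.31; adjusted p = 0.00499, and adjusted p = 0.221 with an estimated correlation). The lower ones were PTGS1, PTGS2 and ACE, whose call was lost without siLATS flow replicate 3 (0.0518). DDAH1, the higher one, lost its call without siNT flow replicate 2 or siLATS flow replicate 1 (up to 0.0567). NRF2 targets had 1 of 14 lower and 0 higher, also adjusted over the list alone (median -0.35; adjusted p = 0.00408, and adjusted p = 0.703 with an estimated correlation), and the 1 was HMOX1 (-2.04). Interferon-stimulated genes had 1 of 22 higher and 0 lower, also adjusted over the list alone (median 0.26; adjusted p = 0.0212, adjusted p = 0.755 with an estimated correlation, 0.0678 without replicate 1 and 0.0819 without both libraries of highest mitochondrial share). It was IFI6 (1.56, adjusted p = 0.0204), lost without siNT flow replicate 1 or 2 or siLATS flow replicate 3 (up to 0.0667). With the replicate block 5 more lists were called. They were SRF/MRTF genes (adjusted p = 0.0868, block 0.0454) and cholesterol synthesis genes (0.245, block 0.0116) toward higher levels, and flow-repressed (0.730, block 0.0389), integrin (0.0622, block 0.0483) and endothelial identity genes (0.0685, block 0.0438) toward lower levels. With an estimated correlation 0 lists were called in this comparison, and these 5 had adjusted p of 0.703 to 0.909.

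The flow response was measured in siLATS cells as well. KLF4 (log2 fold change 4.36, SE 0.196, adjusted p = 1.41e-07), KLF2 (2.55, SE 0.118, adjusted p = 1.41e-07) and NOS3 (2.12, SE 0.103, adjusted p = 2.08e-07) rose, and 19 of 22 interferon-stimulated genes fell. In all, 2831 genes were higher and 2923 lower, of which 723 and 1054 changed by at least 2-fold. Upper-quartile scaling gave 2267 and 3670, with a shift of the median gene of -0.09. The largest rises were CCN3 (6.82, mean 0.176 to 20.6 CPM), CD180 (6.66), DDIT4L (5.46), the microfibril gene MFAP5 (5.38), JPH4 (5.28), SEMA7A (4.95), MYOM3 (4.93), EPN3 (4.88), EXOC3L1 (4.88) and P2RX5 (4.61). The largest falls were MX2 (-6.24), SLC7A14 (-6.08), B3GALT2 (-6.07), RSAD2 (-5.69), CMPK2 (-5.35), MX1 (-5.26), IFIT1 (-5.12), DHRS3 (-5.0), the chemokine CXCL12 (-4.56) and the receptor KIT (-4.54), each with an adjusted p of at most 0.00548.

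In siLATS cells the KLF2/KLF4 programme had 12 of 17 higher and 1 lower under flow (13 and 1 adjusted over the list alone, median 2.42; adjusted p = 9.43e-22, and adjusted p = 0.000800 with an estimated correlation). Interferon-stimulated genes had 19 of 22 lower (20 adjusted over the list alone, median -1.91; adjusted p = 1.66e-14, and adjusted p = 0.338 with an estimated correlation), NRF2 targets 10 of 14 higher (10; 0.97; adjusted p = 5.47e-08, and adjusted p = 0.338 with an estimated correlation) and heat shock genes 8 of 10 higher (8; 0.53; adjusted p = 3.04e-05, and adjusted p = 0.138 with an estimated correlation). SRF/MRTF genes had 10 of 16 lower (11 adjusted over the list alone, median -0.51; adjusted p = 9.98e-05, and adjusted p = 0.364 with an estimated correlation), and NF-kB genes 6 of 17 lower (7; -1.01; adjusted p = 0.00654, and adjusted p = 0.423 with an estimated correlation). YAP/TAZ-TEAD targets had 10 of 21 lower and 3 higher (11 and 4 adjusted over the list alone, median -0.42; adjusted p = 0.0115, and adjusted p = 0.502 with an estimated correlation), including TGFB2 (-3.17). ANKRD1 had 0.19 (adjusted p = 0.476), CCN1 -0.33 (0.149, and 0.0442 without siLATS flow replicate 3), WWTR1 0.12 (0.579) and LATS1 -0.17 (0.463). CCN2 (-0.54, adjusted p = 0.0453) and YAP1 (-0.73, 0.0422) each passed narrowly and lost the call without any of 8 single libraries, among them every siLATS static library, siNT static replicate 1 or 3, and siLATS flow replicate 1 (up to 0.143 and 0.155). For CCN2 the others were siNT static replicate 2 and siLATS flow replicate 2, and for YAP1 siNT flow replicate 3 and siLATS flow replicate 3. EDN1 fell (-1.02, adjusted p = 0.0104).

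Endothelial identity genes had 8 of 18 higher and 2 lower in siLATS cells under flow (9 and 2 adjusted over the list alone, median 0.35; adjusted p = 0.0170, and adjusted p = 0.364 with an estimated correlation), with TEK at 1.94, KDR at 1.62 and VWF at -1.42. Tip cell and angiogenic genes had 8 of 15 higher and 3 lower, also adjusted over the list alone (median 0.55; adjusted p = 0.0407, and adjusted p = 0.415 with an estimated correlation), with the VEGF receptor gene FLT1 at 3.26 and IGFBP3 at -3.69. This list was not called without siLATS static replicate 1 (adjusted p = 0.0717), without replicate 3 (0.101) or without both libraries of highest mitochondrial share (0.0581). Pulmonary arterial hypertension genes had 6 of 10 higher and 1 lower, also adjusted over the list alone (median 0.62; adjusted p = 0.00654, and adjusted p = 0.138 with an estimated correlation), with AQP1 at 2.45, ACVRL1 at 1.26 and BMPR2 at 0.59. Immediate early genes had 5 of 13 higher and 2 lower (6 and 2 adjusted over the list alone, median 0.89; adjusted p = 0.00578, adjusted p = 0.248 with an estimated correlation and 0.151 without replicate 3), with NR4A1 at 4.09 and IER3 at -2.14. Integrin genes had 8 of 17 higher and 2 lower (9 and 2 adjusted over the list alone, median 0.36; adjusted p = 0.0160, and adjusted p = 0.617 with an estimated correlation), with ITGA6 at 2.06 and ITGB3 at -2.35. They were not called without the same pair of libraries (0.0581). Flow-repressed genes had 6 of 12 lower and 3 higher (7 and 4 adjusted over the list alone, median -0.84; adjusted p = 0.0115, and adjusted p = 0.415 with an estimated correlation), with BMP4 at -2.76 and ESM1 at 1.41.

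S-phase genes had 4 of 18 higher and 0 lower in siLATS cells under flow (2 and 0 adjusted over the list alone, median 0.84; adjusted p = 0.0407, adjusted p = 0.909 with an estimated correlation, 0.122 without siLATS static replicate 1, 0.0983 and 0.0953 without replicates 2 and 3, and 0.112 without both libraries of highest mitochondrial share). The 4 were MCM2 (0.91, adjusted p = 0.0152), MCM6, MCM5 and MCM4, and each lost its call without siLATS static replicate 1 or siLATS flow replicate 2 (up to 0.0589, 0.0693, 0.122 and 0.195). MCM6, MCM5 and MCM4 also lost it without siLATS flow replicate 3, MCM5 and MCM4 without siLATS static replicate 3, and MCM4 without siLATS static replicate 2, any siNT static library or siNT flow replicate 3. Smooth muscle and pericyte markers had 3 of 5 lower and 0 higher (4 and 1 adjusted over the list alone, median -2.60; adjusted p = 0.0407, adjusted p = 0.364 with an estimated correlation, 0.138 with the replicate block, 0.105 without replicate 2 and 0.112 without the latter pair of libraries). Those 3 had means of at most 1.39 CPM in any group. Leukocyte markers had 3 of 5 tested members lower and 1, CD68 (0.94), higher, and the 3, PTPRC, LYZ and LST1, were highest of the 12 libraries in siLATS static replicate 1. Cholesterol synthesis genes were called toward higher levels with the replicate block (adjusted p = 0.128, block 0.00844), and not with an estimated correlation (0.914).

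The flow responses of siNT and siLATS cells, which share no library, were compared across genes, which are not independent replicates. Log2 fold changes correlated with a Pearson r of 0.811 and a Spearman rho of 0.796, and 82.0% of genes had the same sign. Of the genes called in siNT, 97.9% had the same sign in siLATS. Called in both were 2070 higher and 2040 lower genes, against 509 and 517 for independent lists, and 9 genes were called in opposite directions. The r and the ratio of root mean square effects, siLATS over siNT, of 1.09 lay outside 20 simulations with equal effects (0.860 to 0.875 and 0.984 to 1.03). With the stricter filter on low counts the r was 0.877, so its place below that range depended on genes of low count. The simulations were not repeated with that filter. The knockdown responses in static and flow correlated with an r of 0.539 and a rho of 0.518, and 69.6% of genes had the same sign. Called in both were 291 higher and 547 lower genes, against 29.9 and 62.1 for independent lists. The slope of the flow on the static knockdown effect, over genes called in static, was 0.571, and the ratio of root mean square effects over genes called in either was 0.780. In 20 simulations with equal effects those values were 0.748 to 0.846 and 0.967 to 1.07. Because fitted noise counted as a shared effect in these simulations, their r and slope can be too high.

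The flow effect in siNT was also set against the static knockdown effect, which use the same 3 siNT static libraries. The r was -0.0616 and the rho -0.0261, where simulated groups with no effect gave a mean r of 0.499 (0.452 to 0.540) from the shared controls alone. The covariance was -0.0294 against a simulated 0.0410, a difference of -0.0704. The simulated groups held no effect of the experiment day, which the real libraries share, so the value to expect without an effect may differ. Of the genes called in both, 430 were higher with flow and lower after knockdown (231 for independent lists), 281 lower and then higher (175), 180 higher in both (178) and 265 lower in both (227). Neither effect had a called gene in any of those simulations, so they set no bound on these overlaps. The 3 control libraries are too few to split. Without replicate 2 the r was 0.0167.

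**Figure D5:**
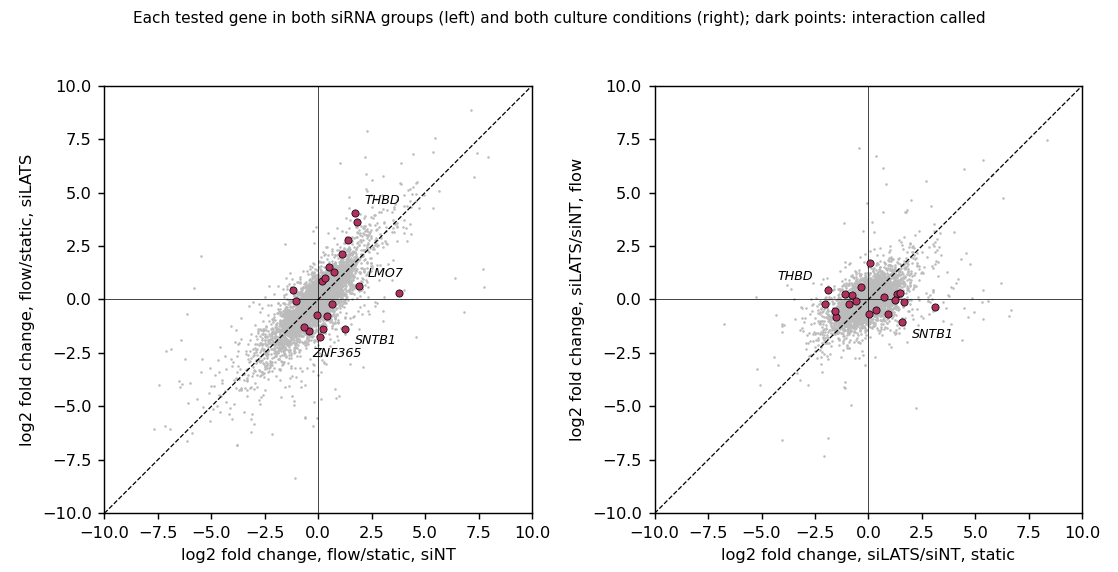
Log2 fold changes of the genes tested, for flow in siNT (x) against flow in siLATS (y) on the left and for knockdown in static (x) against knockdown in flow (y) on the right; each point is a gene, dark points are the 20 interaction genes and the dashed line is equality. The Pearson r was 0.811 on the left and 0.539 on the right.

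Whether the flow response itself depended on the siRNA was tested by the interaction, in which 10 genes were higher and 10 lower in siLATS (108 and 69 with the replicate block, which kept all 20). THBD (chromosome 20, 23045633 to 23049672) rose with flow by a log2 fold change of 1.73 in siNT (51.3 to 170 CPM) and 4.04 in siLATS (13.8 to 228 CPM), a difference of 2.32 (SE 0.282, adjusted p = 0.0319). SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling (chromosome 5, 142310427 to 142326455), rose by 1.80 and 3.64, a difference of 1.84 (SE 0.211, adjusted p = 0.0319). In 11 of the 20 genes the flow effect had the same sign and was larger in siLATS, in 3 it was smaller and in 6 the signs were opposite. An unadjusted p under 0.05 was reached by 1230 genes. Leaving out any 1 of the 12 libraries left at most 6 higher and 3 lower genes, and as few as 0 and 0.

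Other genes with a higher flow effect in siLATS were ABI3 (1.36), the long noncoding RNA gene MANCR (1.03), KIAA1211L (0.99), WDFY4 (0.96), the endothelial transcription factor gene ETS1 (0.70), AFAP1L1 (0.69) and RASIP1, which acts in vessel formation (0.53). Those with a lower effect were ZNF365 (-1.81), the BMP and TGF-beta pseudoreceptor gene BAMBI (-1.58), LMO7 (-1.30), ARID5B (-1.19), the kinase gene MAP3K1 (-1.05), AGPAT2 (-0.86), LRRC32 (-0.68) and ZNF462 (-0.63). The adjusted p-values were 0.0319 to 0.0476. LATS2 rose with flow in siNT (0.58, SE 0.111, adjusted p = 0.00213) and had 0.10 in siLATS (adjusted p = 0.503), with an interaction of -0.48 (adjusted p = 0.445). The interaction was 0.63 for KLF2 (adjusted p = 0.207, block 0.0499), 0.33 for NOS3 (0.593), 0.20 for KLF4 (0.920), 0.29 for EDN1 (0.917), 0.09 for CCN2 (0.972), 0.12 for CCN1 (0.949), -0.40 for ANKRD1 (0.803), 0.17 for YAP1 (0.956), 0.29 for WWTR1 (0.834) and -0.30 for LATS1 (0.829).

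In the interaction 3 lists were called with either correlation. The KLF2/KLF4 programme had 1 of 17 higher (4 adjusted over the list alone, median 0.22; adjusted p = 1.10e-06, and adjusted p = 0.0188 with an estimated correlation), the 1 being THBD. Its call was lost without any siNT static library, siNT flow replicate 2 or 3, siLATS static replicate 2 or 3, or siLATS flow replicate 3 (up to 0.118). Pulmonary arterial hypertension genes had 0 of 10 called over all genes (4 higher adjusted over the list alone, median 0.34; adjusted p = 6.67e-06, and adjusted p = 0.0188 with an estimated correlation), with KDR at 1.14 (adjusted p = 0.0903, block 0.0166) and CAV1 at 0.63 (0.281, block 0.0166). Hypoxia-inducible genes had 0 of 12 called (0 adjusted over the list alone, median -0.31; adjusted p = 0.000638, and adjusted p = 0.0399 with an estimated correlation).

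Another 6 lists were called in the interaction with the preset correlation only. Interferon-stimulated genes (median -0.56; adjusted p = 6.67e-06, and adjusted p = 0.684 with an estimated correlation) had 0 of 22 called and 1 lower adjusted over the list alone. S-phase genes (0.78; adjusted p = 6.67e-06, and adjusted p = 0.684 with an estimated correlation) and mitotic genes (0.64; adjusted p = 0.0360, and adjusted p = 0.863 with an estimated correlation) had 0 of 18 and 0 of 22 called. With the replicate block 3 S-phase genes were called higher, MCM2 (0.93, adjusted p = 0.529, block 0.0258), MCM6 (0.78, 0.529, block 0.0354) and MCM4 (0.95, 0.693, block 0.0499). Unfolded protein and integrated stress response genes (-0.45; adjusted p = 3.95e-05, and adjusted p = 0.600 with an estimated correlation) had 0 of 15 called. These 3 lists also had 0 adjusted over the list alone. Endothelial identity genes (0.22; adjusted p = 0.00217, and adjusted p = 0.392 with an estimated correlation) had 0 of 18 called and 1 higher adjusted over the list alone. Tip cell and angiogenic genes (0.51; adjusted p = 0.0242, and adjusted p = 0.600 with an estimated correlation) had 0 of 15 called and 2 higher and 2 lower adjusted over the list alone, with IGFBP3 at -2.39 (adjusted p = 0.0891, block 0.0189). Smooth muscle and pericyte markers were called lower with the replicate block (adjusted p = 0.0556, block 0.0223), and not with an estimated correlation (0.563). YAP/TAZ-TEAD targets had a median of -0.05 (adjusted p = 0.345). Without siLATS static replicate 1 the adjusted p was 0.394 for mitotic and 0.109 for tip cell genes. Mitotic genes were also not called without replicate 2 (0.152) or 3 (0.0529), nor tip cell genes without replicate 1 (0.634).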

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

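The tests of a weaker knockdown, of chance spread, of a single experiment day and of RNA from blood cells were chosen only after the result was seen, and so were the list tests, correlations and ratio without siLATS static replicate 1. The fits without the 2 libraries of highest mitochondrial share, the fits without the blood-library genes and the comparison of splits that part all pairs were also chosen then. The other tests were planned.

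A difference between the flow effects of siLATS and siNT cells, tested by edgeR's interaction term, marked 20 genes at adjusted p-values of 0.0319 to 0.0476. The log2 difference was 2.32 for THBD, 1.84 for SPRY4, 1.62 for CMAHP, 1.36 for ABI3, 1.03 for MANCR, 0.99 for KIAA1211L, 0.96 for WDFY4, 0.70 for ETS1, 0.69 for AFAP1L1 and 0.53 for RASIP1. It was -0.63 for ZNF462, -0.68 for LRRC32, -0.86 for AGPAT2, -1.05 for MAP3K1, -1.19 for ARID5B, -1.30 for LMO7, -1.58 for BAMBI, -1.81 for ZNF365, -2.63 for SNTB1 and -3.44 for PYY2. CMAHP, PYY2 and SNTB1 had means of at most 2.78 CPM, so these 3 are uncertain and fall outside the rule for naming genes. None of the 20 calls survived every single-library omission, after which 0 to 6 higher and 0 to 3 lower genes were left.

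The same test over gene lists marked 9 lists by camera with a preset correlation. Their median log2 differences were 0.22 for the KLF2/KLF4 programme, -0.56 for interferon-stimulated genes, 0.64 for mitotic genes, 0.78 for S-phase genes, -0.31 for hypoxia-inducible genes, -0.45 for unfolded protein and integrated stress response genes, 0.51 for tip cell genes, 0.22 for endothelial identity genes and 0.34 for pulmonary arterial hypertension genes. With an estimated correlation 3 of these were called.

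The first pattern weighed was that knockdown effects were smaller under flow than in static culture. A weaker knockdown of the transcripts under flow is argued against. The log2 fold changes of LATS1 and LATS2 in flow were 1.12 and 1.23 times those in static. The approximate lower 95% limit of their size in flow, divided by the upper limit in static, was 0.866 and 1.01. All of these values were above the ratio of root mean square effects of 0.780. For LATS2 the larger change came with a rise under flow in siNT, not with a lower level in siLATS. Protein and kinase activity were not measured, so a weaker loss of function under flow stays open. The slope of 0.571 and the ratio of 0.780 lay below the 20 simulations with equal effects (0.748 to 0.846 and 0.967 to 1.07). When each replicate number was left out the ratio was 0.679 to 0.786. Those simulations took fitted effects, noise included, as true and drew genes independently with no effect of the day. Their range can be too high for the slope and too narrow for both values, so chance spread is not excluded. The blood-cell transcripts are argued against by the ratio of 0.779 without the library that held them. An interplay between flow and LATS1/2 loss stays open as a hypothesis, and so do differences in handling between flow and static slides, which were not tested.

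The second pattern was the rise of interferon-stimulated genes after the knockdown in static cells. Without the library holding blood-cell transcripts the median was 1.13 (adjusted p = 1.18e-12, 10 members higher), which argues against those transcripts as the cause. The highest camera adjusted p when each replicate number was left out was 1.03e-08, so the call with the preset correlation did not rest on a single day. This is a weak argument, because that test called up to 12 lists in other splits of the static libraries. The call was lost with an estimated correlation (adjusted p = 0.402), and an effect of the siRNA molecules themselves on interferon signalling, apart from LATS1/2 loss, was not tested and may account for it.

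The third pattern was 184 genes at least 5 times higher in siLATS static replicate 1 than in any other library, where each other library had 0 to 3 such genes. RNA from blood cells is a candidate source, since 7 of the 10 leukocyte markers fixed in advance were highest in that library, and so were 36 of the 40 genes in red cell, neutrophil, lymphocyte and platelet lists (12 of 12, 10 of 10, 6 of 10 and 8 of 8). Those 4 lists were written after blood-cell transcripts were seen, so their counts are no independent test of that source. The most abundant, HBB, HBA2 and HBA1, had 2953, 2590 and 1294 CPM there against at most 30.9, 25.8 and 14.3 elsewhere. These genes do not test a response shared by the 3 static knockdown libraries, because they were chosen as high in 1 of them. LATS1 was at 6.47 CPM in siLATS static replicate 1 and at 9.31 and 6.94 in replicates 2 and 3. LATS2 was at 23.4, 30.6 and 27.0 CPM. Yet each of the 184 genes was by definition at least 5 times lower in replicates 2 and 3. A smaller response of these genes to the knockdown stays open. The 8.15% of genes higher in both other static knockdown libraries than in all 3 static controls decides nothing about it. Only 18 of the 184 passed the count filter, and all were chosen for low levels elsewhere. Of the 18, 4 were called higher in the static knockdown and 12 lower in flow siLATS, and how the RNA came into the library was not tested.

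Other splits of the libraries tested the counts of calls. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 5530 genes for flow in siNT, 2276 for knockdown in static, 1217 for knockdown in flow and 5754 for flow in siLATS, and it was in each case the 1 split with as many genes, since the highest of the others was 0. These counts of 0 decide nothing about chance. Each other split mixes both conditions in each group, which adds the real effect to the spread and leaves few genes to call. For lists the real counts were 11, 13, 6 and 15, the highest others were 14, 12, 13 and 13, and 6, 1, 7 and 1 of the 10 splits gave as many. Among the 4 splits that part all 3 pairs, the highest others were 12, 9, 5 and 8. For the interaction 100 splits were drawn, and 4 called at least 20 genes, a share under 0.05. That share excludes chance less firmly than its size, because splits that mix both siRNAs in a group add the knockdown effect to the spread and so call few genes. Of the 100 splits 17 parted all 3 pairs in both static and flow, the real one among them, too few for a share under 0.05, and the highest of the others called 2 genes. The 3 others called 453, 947 and 1525 genes and point to a structure of the samples. In them every static library kept its siRNA label. Under flow only 1 of the 3 libraries labelled siNT was truly siNT, so that the knockdown effect itself entered the contrast. The count of 9 interaction lists was reached by 49 of the 100 splits (highest other 16, also among the 17), so chance is not excluded for it.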

How the results depend on the processing

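Fits without the libraries of highest mitochondrial share or without the blood-library genes, and list tests and correlations without siLATS static replicate 1, were chosen after seeing the data, and the others were planned. Across 322 results for named genes and 7970 comparisons with alternatives, 7282 kept their side of the threshold, 576 lost the call, 112 gained it and 0 reversed. The replicate block changed 24 of those 322 results, all toward a call, and it ended 3 of the 54 list calls and changed no other call among those 322 results and 54 lists. It also added calls of other lists, which are given with each comparison. Of the 54 list calls 5 held with an estimated correlation and 42 with fry. In 538 comparisons 441 kept the list call.

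With the replicate block the counts of higher and lower genes were 1670 and 2069 for knockdown in static, 994 and 1427 for knockdown in flow and 108 and 69 for the interaction, with 11 lists for knockdown in flow. Fits on only the groups compared gave 1601 higher genes for knockdown in static and 81 and 206 for knockdown in flow. Without the 2 libraries of highest mitochondrial share, knockdown in flow gave 249 and 383 and the interaction 0 and 0. The interaction gave 53 and 39 genes with no filter, 85 and 62 with DESeq2 and 6 and 3 with limma-voom. Called lists with an estimated correlation were 1, 0, 0, 1 and 3 for flow in siNT, knockdown in static, knockdown in flow, flow in siLATS and the interaction, and fry called 3 for knockdown in flow and 3 for the interaction.

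With the stricter filter, the flow responses correlated with r = 0.877 (slope 0.997), the knockdown responses with 0.659 and flow against static knockdown with -0.124. Without the 2 libraries of highest mitochondrial share these were r = 0.763 (slope 0.866) and 0.473, and without the blood-library genes the knockdown slope was 0.590. The cause of these changes was not tested, except that fits without libraries have fewer samples and the stricter filter fewer genes of low count.

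Leaving out single libraries or replicate numbers gave 1240 to 2869 higher and 1240 to 2849 lower genes for flow in siNT, 198 to 1130 and 391 to 1427 for knockdown in static, 2 to 411 and 13 to 716 for knockdown in flow, 1566 to 3031 and 1486 to 3068 for flow in siLATS, and 0 to 6 and 0 to 3 for the interaction. LATS1 had -2.60 to -2.32 in static and -2.94 to -2.51 in flow, and LATS2 -2.24 to -1.97 and -2.72 to -2.42. List tests and correlations were run without each replicate number and without siLATS static replicate 1, but not without each other library. Lists called were 11 to 14, 11 to 14, 5 to 9, 11 to 18 and 8 to 11 in the order above. The flow responses had r of 0.747 to 0.789 and slopes of 0.868 to 0.929, and the knockdown responses r of 0.403 to 0.496, slopes of 0.527 to 0.567 and ratios of 0.679 to 0.786. Flow against static knockdown had r of -0.0573 to 0.0167, the reversal being without replicate 2.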

Other observations

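Genes singled out here were chosen after their values were seen, and apart from ELN these results were not refitted without single libraries. Components of the Hippo pathway moved in both directions with flow in siNT, with 7 of 21 higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.819). The transcription factor gene TEAD3 had a log2 fold change of -2.66 at a mean of 2.29 CPM in siNT static, a low level, and FRMD6 -0.92, while VGLL4 (0.89), AMOTL1 (0.53), LIMD1 (0.52) and SAV1 (0.49) were higher. After the knockdown in static cells 2 of 21 were higher and 4 lower (adjusted p = 0.626), with TEAD1 at 0.84, STK3 at 0.40, MAP4K4 at -0.67, VGLL4 at -0.64, AMOTL1 at -0.47 and LIMD1 at -0.39. In siLATS cells 8 were higher and 6 lower with flow (adjusted p = 0.744), with TEAD3 at -4.57 and VGLL4 at 1.16.

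Vasoactive, mechanosensor and haemostasis genes held large single changes with flow in siNT without a list call. Vasoactive genes had 6 of 13 higher and 4 lower (6 and 5 adjusted over the list alone, adjusted p = 0.507), with PTGS2 at 2.75, PTGIS at -2.93 and ADM at -1.66. Mechanosensor genes had 4 of 12 higher and 2 lower (adjusted p = 0.0698), with HEG1 at 1.56, S1PR1 at 0.80 and CAV1 at -1.03. Haemostasis genes had 5 of 14 higher and 3 lower (adjusted p = 0.454), with F3 at 1.29 and VWF at -1.76. Basement membrane and matrix genes had 4 of 20 higher and 6 lower after the knockdown in static cells (6 and 7 adjusted over the list alone, adjusted p = 0.938), with ELN at 3.32, COL8A1 at 1.10, NID2 at -2.24 and LOX at -0.94. ELN lost its call without siNT static replicate 1 or 3 (adjusted p up to 0.0588).

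Mitotic genes had a mean flow difference whose sign depended on the day, with -0.95, 0.49 and 0.59 in siNT and -0.24, 1.35 and 0.80 in siLATS for replicates 1, 2 and 3. S-phase genes had -0.44, 0.14 and 0.19 in siNT and 0.30, 0.94 and 0.77 in siLATS. The third principal component (10.3% of the variance) set the replicate 1 libraries apart, at 12.9 to 41.6 against at most 2.76 for the others.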
